A study of Rattus norvegicus with 10 samples.

How the data were processed

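Total RNA from rat distal colon was hybridised to a commercial Clontech Atlas array of stress-related genes. The labels divide 10 arrays into 5 called plus E and 5 called minus E, numbered 1 to 5 and 6 to 10. The series title ties the letter E to vitamin E, a family of fat-soluble antioxidants. Dose, duration, route, and whether the arrays carry RNA of separate animals are not given in the sources used here, so p-values measure only the spread between these arrays, which may be partly technical.

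The deposited table holds 1 intensity per probe and array, for 216 probes and 10 arrays, with no blanks and no duplicated probe codes. How the authors scanned the arrays, corrected the background and scaled the deposited intensities is not given in the sources used here. The values behave as linear intensities, from 200.1 to 32018, with many dim probes and few bright ones. Array medians lay between 277.4 and 293.2, a span of 1.06-fold, so the table was taken as already scaled between arrays and used as deposited, by a rule that allowed a span of up to 1.2-fold. No value lies below 200, so a constant of about that size (a background left in or a number added) seems to remain, and it shrinks every ratio of dim probes. Probe means spread over the whole range of the table, so the values were not centred by gene, and how the arrays were rescaled stays unknown. From their range the values were read as signals of 1 colour, so a higher value was taken as more signal on that array.

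The table names probes by code only. Of the 216 codes, 1 is also listed as a synonym of a rat gene in the RefSeq gene table for assembly GRCr8, while no other code of the same form is, and this match was not used. Probes are therefore reported by code. The 16 gene lists fixed before the data were examined could not be filled, and no test of a list was run. The rule for named genes asked for genes with a name, and so named none. In its place, the probes named are those with the smallest p in each direction, limited to 2 per direction. Other probe codes in the text were chosen after their values were seen.

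Values at or below a floor of 212.4, the 5th percentile of all values, were set to the floor, and log2 was taken. Probes above the floor on at least 5 of the 10 arrays were tested, which kept 208 and left out 8. Each was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 208 probes and a threshold of 0.05. Effects are log2 of minus E over plus E, with 95% confidence intervals from the moderated variance. Total signal, median signal, the number of probes above the floor and the share of the 3 brightest probes were compared by exact two-sided permutation tests over all assignments of the 10 arrays to 2 groups of 5, for which the smallest possible p is 0.0079.

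The limma step was tested on simulated data made from the real probes' means and spreads, with 40 of 208 probes changed in each of 50 runs and independent noise between arrays. It called 48.5% of probes changed by 1.1-fold, 96% of those changed by 1.5-fold and 99.1% of those changed by 2-fold on the deposited scale. When no probe was changed it gave 0.04 calls per run. These rates hold for 40 probes changed at once, for dim and bright probes pooled, and for independent arrays. The real arrays deviated together in pairs, so the rates do not give what this comparison could detect. They also do not apply to few changed probes or to bright probes alone.

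Alternatives fixed before the data were examined were quantile normalization, scaling to the median or to the total, a higher floor, a pseudocount, no filter or a stricter filter on dim probes, robust empirical Bayes, array weights, an exact permutation test per probe, and leaving out each array. Scaling to housekeeping genes and all alternatives for gene lists were not run, because gene names for the probe codes are not given in the sources used here. Subtracting the constant of 200, and a block for arrays that deviated together (an exact sign-flip test of the 5 differences for the array-level measures), were added after seeing the data. Array number, not counting of molecules, limits the precision, and no counting interval applies to these intensities.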

Results

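The series measured expression of stress-related genes in the distal colon of rats on 10 arrays, 5 labelled plus E and 5 labelled minus E. The series title ties E to vitamin E, but its dose, duration and route are not given in the sources used here. Intensities of 216 probes were available per array, from a lowest value of 200.1 to a highest of 32018. Of these probes, 117 had a mean intensity under 300 over all arrays, close to the lowest values in the table, and 23 had a mean of 1000 or more. The 3 brightest probes carried between 34.8% and 44.3% of an array's total signal. The median tested probe had a coefficient of variation of 4.98% between arrays of 1 group on the deposited scale. A constant of about 200 left in the values would lower both this figure and the share of the 3 brightest probes. Rank correlations across probes between arrays of the same group ranged from 0.949 to 0.988, and those between arrays of different groups from 0.96 to 0.993. No pair of arrays shared more than 1 identical value, so no array was treated as deposited more than once.

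Overall signal was compared first. Total signal per array was 177739 ± 12582 (SD, n = 5) in plus E and 180372 ± 11005 (SD, n = 5) in minus E, a log2 difference of 0.02 (exact two-sided permutation test, p = 0.69). The number of probes above the floor was 204.6 ± 6.39 (SD, n = 5) in plus E and 205.8 ± 3.7 (SD, n = 5) in minus E (exact permutation p = 0.778). The 3 brightest probes held 40.1% ± 3.42 (SD, n = 5) of the signal in plus E and 40.6% ± 3.46 (SD, n = 5) in minus E (exact permutation p = 0.786). The median signal was 287.2 ± 4.44 (SD, n = 5) in plus E and 281.0 ± 3.64 (SD, n = 5) in minus E, with an exact permutation p of 0.04. After Benjamini-Hochberg adjustment over the 4 array-level measures this p became 0.159 (exact permutation test), above the threshold. The table was taken as already scaled between arrays. Such scaling could have removed a group difference in total signal, median signal or probes above the floor. Tests of those measures therefore compare deposited values only and cannot decide whether signal differed before scaling. A constant left in the values would also shrink a relative difference in total signal.

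The main comparison asked which stress-related genes differ in the colon between the minus E and plus E arrays. None of the 208 probes tested differed between minus E and plus E at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.994. At an unadjusted p under 0.05, limma gave 2 probes, both lower in minus E. Independent arrays with no effect would give 10.4 of 208, but these arrays deviated together in pairs across the groups (arrays 1 and 6 to 5 and 10), and 12 other splits that part those pairs as the real one does gave a median of 1 probe (0 to 7). The exact permutation test per probe gave 2 probes before adjustment and 0 after it. That 0 adds little, since the smallest p this permutation test can give is 0.0079. Many of the 208 probes would have to reach that value together for any to pass. Estimates were higher in minus E for 102 probes and lower for 106, with a median log2 difference of -0.0012. The whole range of estimates ran from -0.24 to 0.28 on the log2 scale.

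The probes with the smallest p in each direction are given for their values, since none passed the test. Probe S1R had an intensity of 348.0 ± 9.97 (SD, n = 5) in plus E and 332.3 ± 8.51 (SD, n = 5) in minus E. Its log2 difference was -0.07 ± 0.026 (SE), with an unadjusted limma p of 0.031 and an adjusted p of 0.994. Probe S31R had 935.8 ± 83.7 (SD, n = 5) in plus E and 831.4 ± 63.1 (SD, n = 5) in minus E, a log2 difference of -0.17 ± 0.073 (SE) with an unadjusted limma p of 0.045 and an adjusted p of 0.994. For S1R and S31R, all 5 minus E arrays lay below the plus E mean, while the ranges of the 2 groups overlapped. Probe R546 had 829.0 ± 106 (SD, n = 5) in plus E and 1010 ± 190 (SD, n = 5) in minus E, the highest estimate of all probes at 0.28 ± 0.14 (SE) on the log2 scale, with an adjusted limma p of 0.994. Probe R590 had 314.2 ± 11.1 (SD, n = 5) in plus E and 325.2 ± 5.94 (SD, n = 5) in minus E, a log2 difference of 0.05 ± 0.027 (SE) with an adjusted limma p of 0.994. Some of these estimates moved by over 1.5 times with the setting. R546 was 0.18 without array 6 of minus E. R590 was 0.03 when arrays were scaled to the same total or a pseudocount replaced the floor, and 0.14 with 200 subtracted, while S1R was -0.04 with the pseudocount and -0.16 with 200 subtracted. The genes behind these probe codes are not named in the sources used here.

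**Figure D1:**
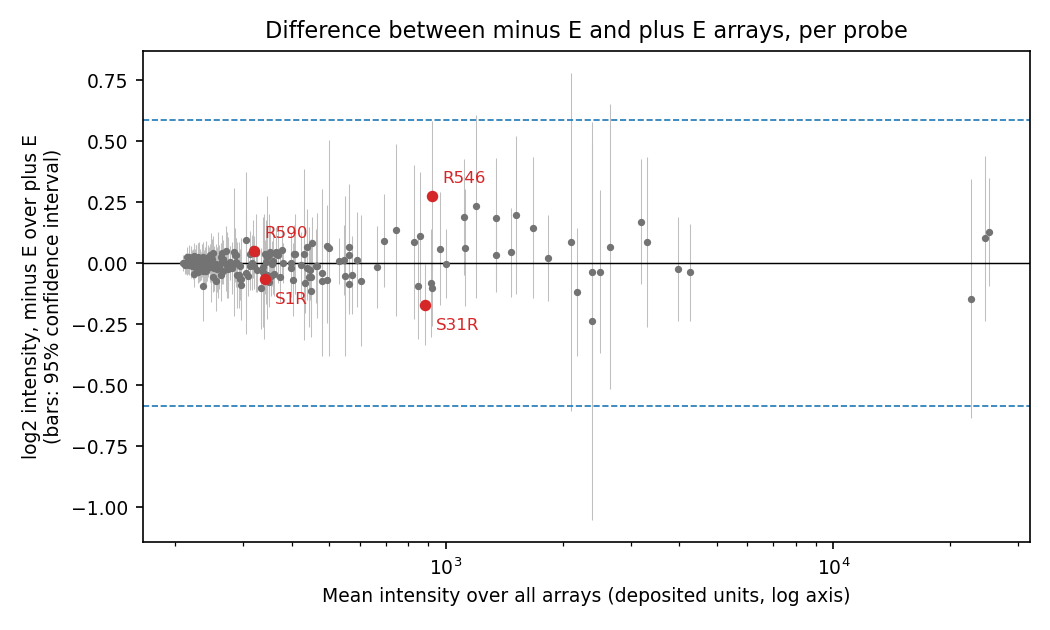
Log2 intensity of minus E over plus E (vertical axis) against mean intensity in deposited units (horizontal log axis) for the 208 probes tested, with 95% confidence intervals as bars, dashed lines at 1.5-fold up and down, and the 4 named probes in red. Estimates lie between -0.24 and 0.28, and the intervals of 203 probes lie between the dashed lines.

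**Figure D2:**
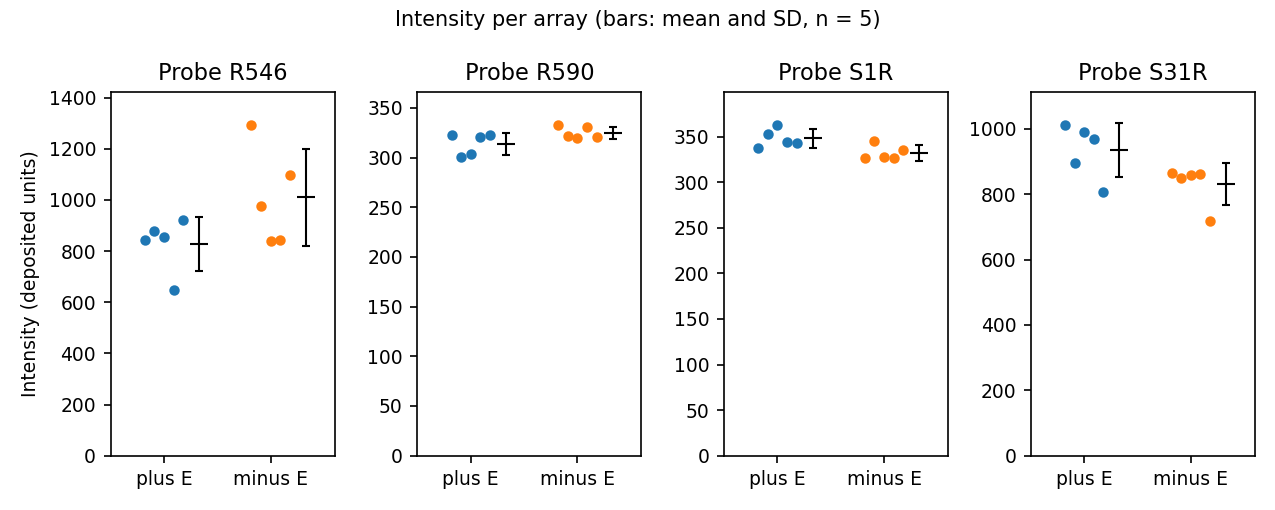
Intensity in deposited units (vertical axis, from 0) of probes R546, R590, S1R and S31R on each of the 5 plus E and 5 minus E arrays, with the mean and SD of each group as black bars. The groups overlap for all 4 probes, and array 10 is the lowest for S31R at 719.0.

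The intervals of the differences give a range for the change of each probe on the deposited scale. They are not adjusted for the number of probes and come from the fit that treats the arrays as independent. They therefore do not exclude larger changes for every probe at once. For 203 of 208 probes the 95% confidence interval lay inside 1.5-fold in either direction, and for 207 inside 2-fold. The 5 probes whose interval reached beyond 1.5-fold were A069, R370, R609, R366 and R367. The widest interval was that of R609, from -1.05 to 0.58 on the log2 scale. R609 was also the most variable probe, with 2564 ± 918 (SD, n = 5) in plus E and 2201 ± 1013 (SD, n = 5) in minus E. R366 came next in variability, with 2064 ± 745 (SD, n = 5) in plus E and 2147 ± 657 (SD, n = 5) in minus E. Bright probes varied more than dim ones, with a median residual SD of 0.13 on the log2 scale for the 99 probes with a mean of 300 or more and 0.039 for the 109 tested probes below it, whose log2 values the constant of about 200 compresses.

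With 200 subtracted, a choice made after seeing the data, 0 of the 99 probes with a mean of 300 or more passed the adjusted threshold in limma, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.966. Estimates then ran from -0.26 to 0.35 on the log2 scale, and the 95% interval lay inside 1.5-fold for 82 of the 99 probes and inside 2-fold for 98. With 200 subtracted and 50 added, all 208 probes could be fitted, 0 passed the adjusted threshold in limma, and the interval lay inside 1.5-fold for 198 and inside 2-fold for 207. The added 50 still shrinks ratios of dim probes. For the 109 tested probes with a mean under 300, detection of a change in the signal above the constant was not tested.

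Arrays also differed in a way that the 2 groups do not explain. After each probe's group means were removed, the deviations of arrays 1 and 6 correlated at 0.64 across the 208 probes. The same correlation was 0.49 for arrays 2 and 7, 0.3 for arrays 3 and 8, 0.37 for arrays 4 and 9, and 0.42 for arrays 5 and 10. These are correlations across probes, and probes are not independent replicates. The labels give no batch and no pairing. With each such pair as a block, a fit added after seeing the data, limma again called 0 probes after adjustment (smallest adjusted p = 0.111) and gave 15 at an unadjusted p under 0.05, of which 7 were higher and 8 lower in minus E. The median signal was lower in minus E in 5 of 5 such pairs, with a mean difference of -6.19 ± 5.01 (SD of the 5 differences) and with a p of 0.0625 in an exact two-sided sign-flip permutation test, the smallest that 5 pairs allow, and 0.25 after adjustment over the 4 array-level measures. The other 3 measures gave exact sign-flip p-values of 0.125 for total signal, 0.875 for probes above the floor and 0.5 for the share of the 3 brightest probes. A test within a pair was not possible, since each holds 1 array per group.

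**Figure D3:**
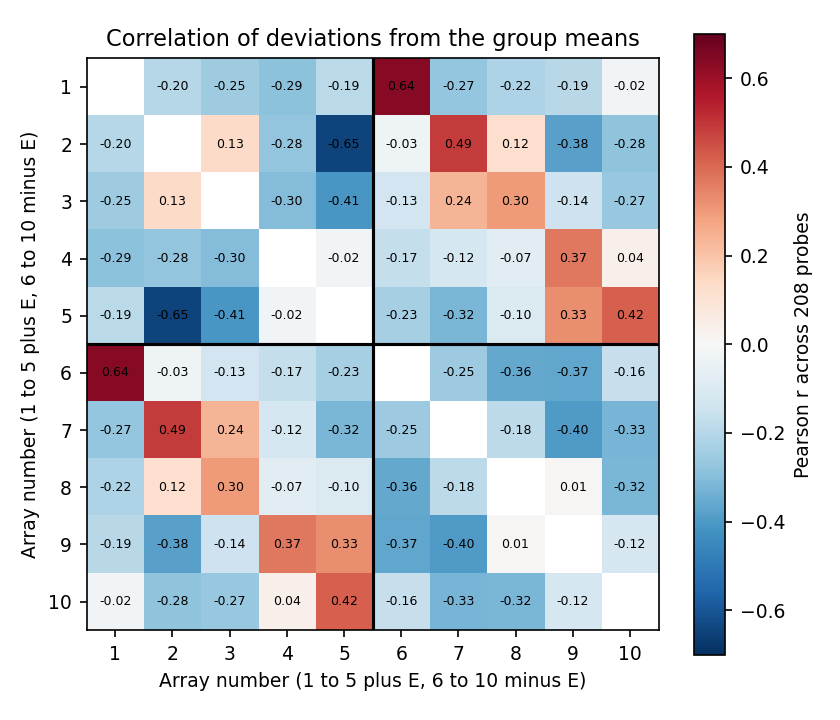
Pearson correlation across the 208 probes of each array's deviations from its group means, for arrays 1 to 5 (plus E) and 6 to 10 (minus E), with the colour scale giving r. The red diagonal in the quadrant between the groups holds arrays at the same place in each group's numbering, from 0.3 for arrays 3 and 8 to 0.64 for arrays 1 and 6.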

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

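Each group of 5 arrays was searched for a single array standing far from the rest, in 16 sets of values (4 array-level measures and 4 named probes in both groups). Chance flags about 1 in 20 such sets. Probe R546 on array 4 of plus E had 647.4, below the 842.9 to 919.5 of the other plus E arrays, a gap of 0.718 of the group's range against a critical value of 0.71. Probe S31R on array 10 of minus E had 719.0, below the 849.8 to 866.7 of the other minus E arrays, a gap of 0.886 of the range. Array 5, at the same place in plus E, was also the lowest of its group for S31R, at 808.2. Without array 10 the log2 difference of S31R was -0.12, against -0.17 with all arrays. Over all 208 probes tested in both groups, 20 of 416 sets (4.81%) had such an array, and no array was the outlying one for more than 4 probes.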

How the results depend on the processing

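Under all 23 alternatives run, limma or the exact permutation test called 0 probes after adjustment, as in the main comparison. Leaving out 1 array gave 0 calls each time, with the smallest adjusted p between 0.706 and 1.0. The count at an unadjusted p under 0.05 was 2, and ranged from 0 (200 subtracted, bright probes) to 15 (arrays at the same place as a block), with 7 under array weights and 1 to 8 when 1 array was left out (8 without plus E array 5). Which probes are counted can change with the setting, and the balance of directions among them varied too. Quantile normalization gave 0 higher and 3 lower in minus E, robust empirical Bayes 1 higher and 1 lower, and leaving out minus E array 9 gave 1 higher and 0 lower. The 4 named probes kept their direction under every alternative, but not their size, and none passed. The difference in total signal turned to -0.031 on the log2 scale (exact permutation p = 0.04, unadjusted) when the median replaced the total. It ranged from -0.015 to 0.058 when 1 array was left out, turning negative without plus E array 5 or minus E array 8. The difference in probes above the floor ranged from -1.45 to 2.65 when 1 array was left out, turning negative without plus E array 5. Scaling moved the median difference of all probes to -0.02 at most (scaling to the same total). The labels give the 2 groups no shared numbers, so the block rests on a likeness seen in the data. Scaling to housekeeping genes and the gene list alternatives were not run, since the sources used here name no genes. Signal near the constant of about 200 limits the 117 probes with a mean under 300.

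Splitting the 10 arrays into other groups of 5 did not single out the real grouping. Of 100 splits drawn from 126, the real one included, 89 gave at least its 2 probes at an unadjusted p under 0.05 (highest other, 52), so chance is not excluded for that count, though most of these splits keep some same-place arrays together. All 100 necessarily reach the real split's 0 adjusted calls (highest other, 10), which decides nothing. The split with 52 set arrays 1, 2, 3, 6 and 7 against the rest, many times the real count, which points to a structure among the arrays other than the groups.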

Other observations

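Gene names for the probe codes were not used here, so no gene groups are described. The pairwise likeness of arrays was noticed in the data and the test of a shared source was chosen after it was seen, while the outcomes to expect of the brightness and dim-probe tests were set before they were run.

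Arrays at the same place in the numbering of the 2 groups deviated together, with a mean correlation of 0.44. The mean for other pairs of arrays between the groups was -0.11. Removing the group means forces about that value once the same-place mean is given, so it adds no evidence. Of the arrays in the other group, 10 of 10 arrays correlated best with the one at their own place. The pairing was not clear-cut throughout, since arrays 5 and 9 correlated at 0.33, above the 0.3 of arrays 3 and 8. The next-best one-to-one matching of arrays between the groups had a mean correlation of 0.357. Different brightness distributions of the arrays are argued against as the whole cause, since the mean correlation was 0.419 after quantile normalization. A likeness carried only by probes near the constant of about 200 is argued against too. The mean correlation was 0.529 on probes with a mean of 300 or more and 0.359 on the tested probes below it. Noise independent between arrays could only weaken such a correlation, so these values decide nothing about it. A shared hybridisation run, a membrane used again or a shared animal source remain open: the same-place matching had the highest mean correlation of the 120 one-to-one matchings (share 0.00833, the smallest they can give), but the labels record none of these, so they cannot be told apart. No biological explanation was tested, since the design names no factor besides vitamin E.

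If the arrays were handled in such pairs, the comparison without a block may carry their spread as error. Place in the numbering took 78.6% of the variance over all probes (44.4% by chance for that many terms), and group took 6.14% (11.1% by chance). These shares pool the probes, so the most variable ones weigh most and a typical probe may differ. The chance value for place holds for a pairing fixed in advance, while this one was noticed in the same data. Among the other splits drawn, the 12 that part all 5 same-place pairs, as the real one does, had a median of 1 probe (0 to 7) at an unadjusted p under 0.05, against the real 2 and a median of 9 for splits that do not. With place as a block the median standard error fell from 0.044 to 0.028 on the log2 scale. The 95% interval of all 208 probes lay inside 1.5-fold on the deposited scale. That scale keeps the constant that compresses dim probes, and no blocked fit with the constant subtracted was run. The narrower intervals also rest on a pairing noticed in the same data. In the blocked fit 15 probes had an unadjusted p under 0.05, against 10.4 expected if pairs are independent. Probe S31R then had the smallest p in limma, 0.00054 unadjusted and 0.111 adjusted, at a log2 difference of -0.17. The other named probes had unadjusted limma p-values of 0.021 (R546), 0.027 (S1R) and 0.0499 (R590), each with an adjusted p of 0.627. All were named for small p-values in these same data. The difference between minus E and plus E had 1 sign in all 5 same-place pairs for 12 probes. Chance gives about 13, or fewer where values tie at the floor. That count covers all probes and ignores the size of a difference, so it decides nothing about S31R. S31R did not pass the correction, and the block was chosen after seeing the data, so it is only a hypothesis for follow-up.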
